A study of Chlamydomonas reinhardtii with 20 samples.

How the data were processed

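Total RNA of Chlamydomonas reinhardtii CC1690 was labelled with Cy3 and hybridised to single-colour Agilent arrays. The labels give 20 arrays of 18 biological samples in 6 groups of 3. These are the high light reactor at 0, 40, 120 and 480 min and the low light reactor at 0 and 480 min. Per the labels all cultures grew at 41 µmol of photons per square metre and second before the shift, and the shift was to 145. The spot intensities in the deposited array files were made by the authors with Agilent Feature Extraction 10.7.3.1, and per the file headers the processed intensity is background-subtracted and detrended within the array, with a surrogate value where a spot is not above background, and not normalized between arrays. The authors also deposited a matrix of log2 values normalized between arrays, by a method that the files do not state. The raw mean spot intensity and local background intensity in the same deposited files were used for 1 alternative only.

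The main values were log2 of the processed intensity minus the array's 75th percentile over the 43801 non-control spots. Technical arrays of a sample were averaged on the log2 scale. The array design holds 3 probes for each of 14557 gene models and 18 probes without a gene model. Each model was measured by the probe with the highest mean log2 signal over all samples, which was probe number 1 for 6260 features, number 2 for 3404 and number 3 for 3883. Probe number 3 overlaps its model's other probes on the opposite strand in 912 models, and 167 tested features rest on such a probe. In 10521 it overlaps none, so 167 may be too low. A feature was kept when it was well above background, by the flag in the files, in every sample of at least 1 group, which left 13565 of 14575 features. Few arrays per group limit the precision of every value.

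Gene models were matched to the reference table of the assembly Chlamydomonas_reinhardtii_v5.5 through its older locus tags, which gave a locus tag to 12302 models. The array's models belong to an older assembly, so the table was used for names and gene order only. Neither the files nor the table give gene symbols, so the 33 lists of symbols written before the data were examined could not be matched. After the files were opened, but before any comparison was run, 145 proteins of conserved families in 27 lists were written down from general knowledge and the probe sequences were searched against them with blastx 2.17.0, keeping matches of at least 28 bits and 60% identity on the best protein. This matched 232 gene models to 78 proteins, and 0 models to the same proteins reversed. Lists with at least 3 measured members were tested, which were 11. The matches name a family, not a gene, and related genes can cross-hybridise.

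One linear model with a mean per group was fitted to all 18 samples with limma 3.58.1 in R 4.3.3, with moderated two-sided tests and Benjamini-Hochberg adjustment within each of 9 comparisons. A feature was called at an adjusted p under 0.05, and calls with a log2 change of at least 1 were counted as well. The comparisons were 40, 120 and 480 min against 0 min, 120 against 40 min and 480 against 120 min in the high light reactor, 480 against 0 min in the low light reactor, the reactors at 480 and at 0 min, and the difference of the 480 min changes between reactors. Lists were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a set moves on balance without comparing it with other genes. Overlaps between times were set beside the number for independent lists, 20 simulations of unchanged groups against the same controls, and a repeat with the low light 0 min samples as control of 1 time.

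The design, the tests, the symbol lists, the naming rule and most of the alternatives below were fixed before the data were examined. The replicate numbers come from the sample titles, which speak of replicate series but do not say that a number marks a shared day or inoculum across groups. Deviations from the group mean correlated at a median of 0.104 over the 45 pairs of samples with the same number (23 above 0.1) and -0.0425 over the 90 pairs of other numbers, and 14 of 18 samples correlated best with their own number. Each pair of one number correlated above 0.1 only in 3 comparisons, which were 120 against 0 min, 480 against 0 min in low light and the reactors at 0 min. The numbers were taken to pair the samples in those, and the replicate was fitted as a block as an alternative everywhere. The first number in each array's label takes 5 values with 4 arrays each and was taken for the slide, which the labels do not state. It was fitted as a term, and changes were computed within each slide that held both groups.

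Genes were named by a rule. In each comparison it took, among genes with a family match, the 8 largest rises and 8 largest falls that were called, had groups without overlap and were well above background in the brighter group. It added up to 2 called members of each list in either direction, the families of PSBS, the Rubisco small subunit, carbonic anhydrase and HSP70 whether called or not (other genes fixed for this had no match), and at most 2 rises and 2 falls of features with an ID only. Members of the first set that belong to the histone and ribosomal protein lists were left to the counts of those lists where camera called them. The rule gave 237 values, and 135 of these are named in the text. Which of the remaining members were named was decided after their values had been seen, so the effect of the alternatives is given for the full set as well.

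Alternatives changed 1 choice at a time. They were normexp background correction with an offset of 50, quantile normalization, a percentile over probes well above background on all arrays, the authors' own values, no filter or a stricter filter on dim probes, the replicate or the slide as a block, the first technical array only, the mean of the probes of a gene, all probes singly, only the groups compared, the 0 min samples of both reactors pooled, limma with trend and robust variance, and leaving out each sample in turn. Added after the data were seen were the use of probes number 1 and 2 only and, for the models with a family match that are measured by another probe (22 of the 33 named ones), the probe with the match. For the lists these 2 choices were added, the slide as a term, histones joined to 1 mean per type, and leaving out each sample in turn. Simulated data on 13565 features with 200 changed genes, made like the comparison of 40 with 0 min, were used as a test of the code. There limma recovered 17.9% of genes changed by a log2 of 0.5, 83.6% of those changed by 1 and 98.5% of those changed by 2, and 4.32% of the calls were unchanged genes. Other tools were data.table (version 1.17.8), statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Left out were control spots, for want of a gene, and coordinates, since no sequence of the array's assembly was at hand.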

Results

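Transcripts of the green alga Chlamydomonas reinhardtii, strain CC1690, were measured before and during a shift of the cultures from 41 to 145 µmol of photons per square metre and second. A high light reactor was sampled at 0, 40, 120 and 480 min, and a second reactor that stayed in low light at 0 and 480 min. This gave 6 groups of 3 biological replicates, 18 samples in all, on 20 single-colour Agilent arrays, since replicate 1 at 0 min and at 40 min in the high light reactor was run on 2 arrays each. The array carried 14557 gene models, and 13565 features passed the filter on dim signals. The 75th percentile of the intensity was 429 to 909 per array. High light reactor arrays had 550 to 573 at 0 min and 807 to 909, the highest, at 480 min. Of the spots 69.5% to 83.7% were well above background, with 0 saturated. Log2 signals of the technical arrays correlated at 0.995 across genes, those of samples of 1 group at 0.982 to 0.995 and those of samples of different groups at 0.958 to 0.995. Genes are not independent replicates. A gene's p-value measures the spread between samples, and the number of arrays limits the precision. Camera's p for a list compares it with other genes, at a preset correlation unless stated. Each p of a list is adjusted over the lists within its comparison.

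The files name the probes by gene model and the reference table pairs 12302 of these models with a locus tag, but neither gives gene symbols. Protein families were therefore assigned by translating the probes, and a family name below rests on a match of a short stretch of protein, 12 residues for the PSBS match and 19 for the cytochrome c6 match. Related genes can hybridise to the same probe. Each gene model was measured by the brightest of its 3 probes, and for 22 of the 33 named models this is another probe than the one with the match. The matching probe of such a model was therefore used in its place as a further alternative, and its value is given where the outcome differed. Changes are log2 differences between group means with their standard error (SE, n = 3 samples per group), and a gene was called when limma gave a Benjamini-Hochberg adjusted p under 0.05. Groups that do not overlap have every sample of one group above every sample of the other, which chance alone gives for 10% of genes.

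The samples spread mainly by time after the shift. The first principal component held 45.9% of the variance, the second 17.3% and the third 8.99%. On the first component the 40 min samples lay at 54.6 to 63.4 and the 120 min samples at 36.4 to 41.2. The 480 min samples of the high light reactor lay at 1.96 to 9.61, and all 9 samples kept at 41 µmol, with those of the high light reactor at 0 min among them, at -40.7 to -31.2.

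**Figure D1:**
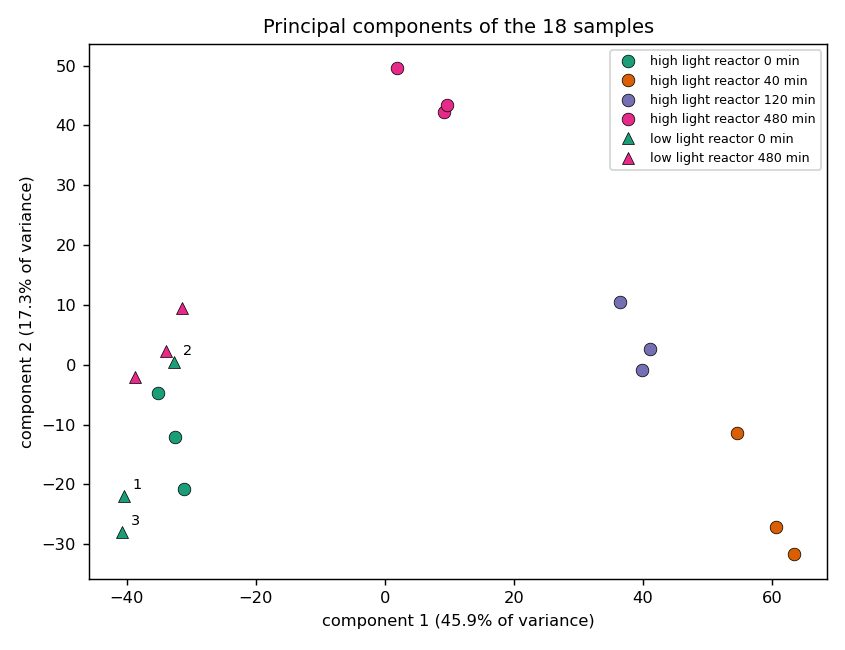
Position of each of the 18 biological samples on the first and second principal component of the log2 signals (no unit), with 1 symbol per sample, circles for the high light and triangles for the low light reactor, 1 colour per time and the replicate number beside the low light 0 min samples. The 40 min samples lie farthest right (54.6 to 63.4) and the low light and 0 min samples farthest left (-40.7 to -31.2).

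The first comparison asked what had changed 40 min after the increase in light. The match to the photoprotective protein PSBS rose, and so did 3 of 4 genes of the heat shock and chaperone list and 7 of 10 of proteasome and ubiquitin. Transcripts matched to an enzyme of chlorophyll synthesis and to glutamate synthase fell. There was no low light sample at 40 min, so light and elapsed time were not separated here. Of 13564 features, limma called 5999, with 2591 up and 3408 down, and 937 of these rose and 1313 fell by a log2 of at least 1. The groups did not overlap in 7645 features (56.5%, against 10% by chance), 5881 of them called. With the slide as a term 5567 were called, and within each of the 3 slides that held both groups at least 99.3% of the called genes kept their direction (here and below, of those with a value on the slide). Groups without overlap fix this, and at least 96.8% of called genes had them in each comparison of groups. By detection, 6 features were well above background in every 40 min and no 0 min sample, and 92 the other way round.

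Among the genes with a family match, the PSBS match CHLRE_01g016750v5 rose most at 40 min, by a log2 of 5.61 (SE 0.31, limma adjusted p 1.93e-09). An actin match, CHLRE_03g176833v5, rose by 4.59 (SE 0.37, adjusted p 7.61e-08). A chaperonin 60 match, CHLRE_06g309100v5, rose by 2.15 (SE 0.19, adjusted p 2.24e-07) and an HSP70 match, CHLRE_09g393200v5, by 1.80 (SE 0.15, adjusted p 9.19e-08, or 0.53 with 0.0014 on the matching probe). The stearoyl-ACP desaturase match CHLRE_14g630883v5 rose by 1.99, the starch synthase match CHLRE_17g721500v5 by 1.61, the glutathione peroxidase match CHLRE_10g458450v5 by 1.37 and the cytochrome c6 match CHLRE_16g651050v5 by 1.36, with adjusted p values from 1.9e-06 to 7.84e-04. On its matching probe the cytochrome c6 model changed by 0.45 and was uncalled (adjusted p 0.266). Proteasome alpha subunit matches CHLRE_01g030850v5 and CHLRE_17g724350v5 rose by 1.15 each. The carbonic anhydrase match CHLRE_03g145067v5 rose by 0.72 (adjusted p 3.89e-04), but by 0.11 (adjusted p 0.612) in the authors' own values. Only probe number 1 of this model matched, over 10 residues read on the strand opposite to the probe, so its signal need not be that of a carbonic anhydrase transcript. Both Rubisco small subunit matches stayed uncalled, CHLRE_02g120150v5 at -0.10 (adjusted p 0.620) and >108283 at -0.07 (adjusted p 0.656). Among the features that have an ID only, CHLRE_01g016600v5 rose by 8.08 and CHLRE_03g152750v5 by 7.10. CHLRE_16g681351v5 changed by -6.42, with 2 of its 3 samples well above background at 40 min, and CHLRE_06g263200v5 by -5.21.

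The protochlorophyllide reductase match CHLRE_01g015350v5 changed by -1.06 (SE 0.16, limma adjusted p 5.48e-05) and the glutamate synthase match CHLRE_05g237100v5 by -0.86 (SE 0.16, adjusted p 3.32e-04) at 40 min. Smaller falls were those of the Rab-type GTPase match CHLRE_11g482900v5 (-0.64, adjusted p 5.57e-04, but uncalled on the matching probe at -0.52 with 0.0918) and the thioredoxin match CHLRE_06g282651v5 (-0.63, adjusted p 0.00382). Only probe number 3 of the latter matched thioredoxin, over 12 residues read on the opposite strand, while its values come from probe number 2, so the name is uncertain, and on probe number 3 the change was 0.028 (0.972). The other falls depended on single samples and on the processing. The calmodulin match CHLRE_03g178350v5 changed by -0.64 (adjusted p 0.0143), or -0.53 (0.0660) without 40 min replicate 2, -0.45 (0.205) on probes number 1 and 2, -0.45 (0.209) on its matching probe and -0.54 (0.129) in the authors' values. The elongation factor 1 alpha match CHLRE_06g259200v5 changed by -0.51 (adjusted p 0.0194). Its call was lost without 0 min replicate 2 (0.0678), 0 min replicate 3 (0.0584) or 40 min replicate 3 (0.0576), and after quantile normalization (-0.43, 0.0944). The glutamate semialdehyde aminotransferase match CHLRE_03g158000v5 changed by -0.32 (adjusted p 0.0163), and lost its call without 0 min replicate 3 (0.0659) or 40 min replicate 1 (0.0896), on probes number 1 and 2 (-0.28, 0.0554) and on its matching probe (-0.18, 0.292). The ribosomal protein S11 match CHLRE_12g514500v5 changed by -0.22 (adjusted p 0.0466). It lost its call in 13 of the 18 fits that left out 1 sample (up to 0.164), namely all but those without 40 min replicate 3, high light 480 min replicate 1 or a low light 0 min sample. It also lost its call after normexp (-0.16, 0.167), with the replicate as a block (0.0545), with slide as a term (0.140) and in the authors' values (-0.19, 0.0587).

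At 40 min camera found 2 of 11 gene lists shifted. Heat shock proteins and chaperones rose, with a median log2 of 1.44 over 4 genes, 3 called up over all genes and adjusted over the list alone (adjusted p 0.0153). Their shift against other genes was 1.54, 1.33 and 1.79 within slides 1, 3 and 5, and with slide as a term p was 0.00967. Proteasome and ubiquitin rose, with a median of 0.53 over 10 genes, 7 called up over all genes and 8 adjusted over the list alone (adjusted p 0.00424). The shift was 0.68, 0.69 and 0.68 within the same slides, and 0.00351 was the p with slide as a term. With the correlation between genes estimated from the data, the adjusted p was 0.0569 for either list. None of the 4 heat shock and chaperone genes and 3 of the 10 of proteasome and ubiquitin are measured by a matching probe. On the matching probes the median of the former was 0.87 (4 called up, adjusted p 0.0452) and that of the latter 0.43 (7 up and 1 down, adjusted p 0.103, no call). Across all comparisons camera made 20 list calls with its preset correlation of 0.01, and 1 of them held with an estimated correlation, that of the heat shock proteins at 120 min. On the matching probes 14 of the 20 were called in the same direction. No list call made below should be read as independent of that setting.

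At 120 min the question was whether the first changes lasted. On the probes used, 4 of 4 genes of the heat shock and chaperone list and 5 of 10 of proteasome and ubiquitin were called up, and on the matching probes 3 and 4. The PSBS match was lower than at 40 min but far above the start. Called below the start were 94 of 137 histone models and 25 of 26 cytosolic ribosomal protein genes. No low light sample was taken at this time either. Limma called 5536 of 13564 features, 2531 up and 3005 down, with 652 and 835 of them changed by a log2 of at least 1. The share called up was 45.7%, 51.7% in the authors' values and 38.0% after normexp, so which direction held more calls depended on the processing. The groups did not overlap in 8244 features (60.9%, against 10% by chance). A slide term left 4828 calls, and at least 99.6% of the called genes kept their direction within slides 1 and 5. With the replicate, which paired these samples, as a block 5731 were called. By detection 14 features appeared and 29 disappeared.

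The actin match CHLRE_03g176833v5 was up by 3.69 at 120 min and the PSBS match CHLRE_01g016750v5 by 3.37 (SE 0.31, limma adjusted p 8.49e-07). The chaperonin 60 match CHLRE_06g309100v5 was up by 2.51 (SE 0.19, adjusted p 1.05e-07) and the HSP70 match CHLRE_09g393200v5 by 2.25 (SE 0.15, adjusted p 2.48e-08, or 0.53 with 0.00199 on the matching probe). The cytochrome c6 match CHLRE_16g651050v5 was up by 2.02 (but by 0.37 with 0.358 on the matching probe), the glutathione peroxidase match CHLRE_10g458450v5 by 1.66, and the proteasome alpha subunit matches CHLRE_01g030850v5 and CHLRE_17g724350v5 by 1.57 and 1.55. The calmodulin match CHLRE_03g178350v5 changed by -1.31 (SE 0.19, adjusted p 7.83e-05) and the ribosomal protein S11 match CHLRE_12g514500v5 by -0.56 (SE 0.09, adjusted p 1.09e-04). With an ID only, CHLRE_08g365900v5 rose by 5.43 and CHLRE_13g603550v5 changed by -6.63.

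Camera found 4 lists shifted at 120 min. Heat shock proteins and chaperones had a median of 1.64, with all 4 genes called up over all genes and adjusted over the list alone (adjusted p 5.88e-04, 0.0263 with an estimated correlation). Within slides 1 and 5 their shift was 1.64 and 1.77, and p with slide as a term was 3.7e-04. On the matching probes the median was 0.76 (3 called up, adjusted p 0.0142). Proteasome and ubiquitin had a median of 0.40, with 5 genes called up over all genes, and 5 up and 1 down adjusted over the list alone (adjusted p 0.00856, estimated 0.132, slide term 0.00966, within-slide shifts 0.25 and 0.62), but 0.04 on the matching probes (4 up and 2 down, adjusted p 0.357, no call). Cytosolic ribosomal proteins had a median of -0.39 over 26 genes, with 25 called down over all genes and 26 adjusted over the list alone (adjusted p 5.32e-06, estimated 0.486, slide term 4.37e-05, within-slide shifts -0.22 and -0.33). After quantile normalization their median was -0.11 and the p was 0.0712. Histones had a median of -0.54 over 137 gene models, with 94 called down over all genes and 98 adjusted over the list alone (adjusted p 1.65e-09, estimated 0.823, slide term 8.09e-07, within-slide shifts -0.81 and -0.15). Histone models are near copies of each other with an estimated correlation that leaves few independent values, and when they were joined to 1 mean per histone type the p was 0.193.

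At 480 min the comparison with 0 min asked what remained after 8 h of high light. Among genes with a family match the cytochrome c6 match had the largest rise on the probes used, though not on the matching ones, and PCNA, a protein of DNA replication, was up. The chaperonin 60 match was still raised, while the list of heat shock proteins and chaperones was not called (adjusted p 0.108). Ribosomal protein transcripts were down under every scaling tried, by an amount that depended strongly on the scaling. Limma called 5868 of 13564 features, 2356 up and 3512 down, with 618 and 635 of them changed by a log2 of at least 1. The share called up was 40.1%, and 30.0% after normexp background correction. The groups did not overlap in 7837 features (57.9%, against 10% by chance). A slide term left 5165 calls, and at least 99.6% of the called genes kept their direction within slides 3 and 4. By detection 18 features appeared and 30 disappeared.

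The cytochrome c6 match CHLRE_16g651050v5 was up by 4.07 at 480 min (SE 0.28, limma adjusted p 1.1e-07) and the actin match CHLRE_03g176833v5 by 3.18 (SE 0.37, adjusted p 1.06e-05), and on their matching probes by 1.48 (0.00124) and 2.79 (2.6e-05). The glutathione peroxidase match CHLRE_10g458450v5 was up by 1.52, the PCNA match CHLRE_12g515850v5 by 1.34, the proteasome alpha subunit matches CHLRE_17g724350v5 and CHLRE_01g030850v5 by 1.27 and 1.24, and the chaperonin 60 match CHLRE_06g309100v5 by 1.19. The HSP70 match CHLRE_09g393200v5 was up by 1.1, but by 0.17 (adjusted p 0.243) on the matching probe, the glutamate synthase match CHLRE_05g237100v5 by 0.96 and the carbonic anhydrase match CHLRE_03g145067v5 by 0.64. The PSBS match CHLRE_01g016750v5 was up by 1.1 (SE 0.31, adjusted p 0.0101), and by 0.61 (adjusted p 0.0368) without 480 min replicate 3. The MCM helicase match CHLRE_03g178650v5 was up by 1.44 (SE 0.51, adjusted p 0.0328). Its adjusted p was 0.0947 with slide as a term, 0.0876 without 0 min replicate 2, 0.116 without 0 min replicate 3, and 0.0661, 0.0692 and 0.0734 without 480 min replicate 1, 2 or 3. With an ID only, CHLRE_03g162800v5 rose by 5.65 and CHLRE_04g222750v5 by 4.88.

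The elongation factor 2 match >107717, which rests on 16 residues at 75% identity, changed by -2.25 at 480 min (SE 0.20, limma adjusted p 1.49e-06). The biotin carboxylase match CHLRE_08g359350v5 changed by -1.03 (SE 0.31, adjusted p 0.0132), with an adjusted p of 0.0549 without 0 min replicate 2 and 0.0583 without 480 min replicate 3, and it turned to 0.16 (adjusted p 0.441) in the authors' own values. The ribosomal protein S11 match CHLRE_12g514500v5 changed by -0.84 and the thioredoxin match CHLRE_06g282651v5 by -0.76, or by 0.12 (adjusted p 0.878) on its matching probe. The Rubisco small subunit matches >108283 and CHLRE_02g120150v5 changed by -0.75 (adjusted p 7.29e-05) and -0.73 (adjusted p 0.00119). After quantile normalization the 2 were at -0.11 (adjusted p 0.248) and -0.07 (adjusted p 0.59), and in the authors' values CHLRE_02g120150v5 was at -0.10 (adjusted p 0.340). With an ID only, CHLRE_13g603550v5 changed by -6.02 and CHLRE_12g492050v5, which was not above background in any 480 min sample, was at least 9.71-fold lower.

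Camera found 3 lists shifted at 480 min. Cytosolic ribosomal proteins had a median of -0.70, with 26 of 26 called down over all genes and adjusted over the list alone (adjusted p 1e-11, estimated 0.321, slide term 3.85e-10, within-slide shifts -0.63 and -0.49). After quantile normalization the median was -0.13 and the p was 0.0704, and in the authors' values the median was -0.16. Histones had a median of 0.38, with 13 called up over all genes and 0 adjusted over the list alone (adjusted p 8.82e-10, estimated 0.520, slide term 2.65e-08, within-slide shifts 0.27 and 0.22). Joined to 1 mean per type their p was 0.157. The Calvin-Benson cycle list had a median of -0.65 over 6 genes, with 4 called down over all genes and 5 adjusted over the list alone (adjusted p 0.0253, estimated 0.384, slide term 0.0476, within-slide shifts -0.48 and -0.55), but after quantile normalization its direction against other genes was up (p 0.661).

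**Figure D2:**
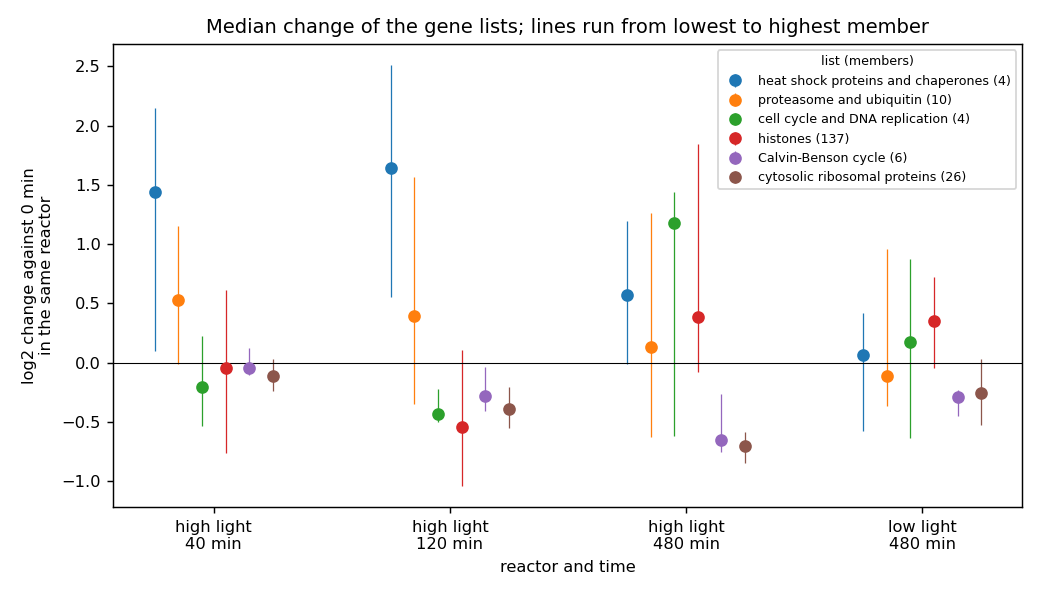
Log2 change against 0 min in the same reactor (vertical axis) of the 6 gene lists that camera called in some comparison, by reactor and time, with a point for the median and a line from the lowest to the highest member. Heat shock proteins and chaperones had medians of 1.44 and 1.64 at 40 and 120 min, and cytosolic ribosomal proteins lay at -0.70 at 480 min in high light, a value that shrank to -0.13 after quantile normalization, and at -0.26 in low light, which turned to 0.03.

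Between 40 and 120 min the comparison asked whether early changes turned back. The PSBS match fell, and the matches to protochlorophyllide reductase and glutamate synthase, which had fallen first, rose. Limma called 3821 of 13564 features, 2214 up and 1607 down, with 417 and 387 of them changed by a log2 of at least 1. The share called up was 57.9%, but 48.6% after normexp and 66.6% when the scaling percentile was taken over probes well above background on all arrays, so which direction held more calls depended on the scaling. The groups did not overlap in 6468 features (47.8%, against 10% by chance). A fit with a slide term called 3310, and at least 99.6% of the called genes kept their direction within slides 1, 2 and 5. Of the 2591 genes up at 40 min, 1018 were called down from 40 to 120 min, and of the 3408 down at 40 min, 1377 were called up. Both comparisons use the 40 min samples, whose chance deviations alone give changes of opposite sign. By detection 53 features appeared and 1 disappeared.

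From 40 to 120 min the PSBS match CHLRE_01g016750v5 changed by -2.24 (SE 0.31, limma adjusted p 8.07e-05) and the alternative oxidase match CHLRE_03g169550v5 by -1.04 (SE 0.13, adjusted p 3.58e-05), but it was uncalled in the authors' values (-0.42) and on its matching probe (-0.01, 0.989). With an ID only, CHLRE_03g152750v5 changed by -6.18. The glutamate synthase match CHLRE_05g237100v5 rose by 1.08, the Rab-type GTPase match CHLRE_11g482900v5 by 0.77, the protochlorophyllide reductase match CHLRE_01g015350v5 by 0.69 and an actin match other than the one above, CHLRE_06g249300v5, by 0.45, with adjusted p values from 1.18e-04 to 0.00424. Another 4 rises were close to the threshold and depended on single samples. The HSP70 match CHLRE_09g393200v5 rose by 0.45 (adjusted p 0.0293), and lost its call without 120 min replicate 1 (0.0888), 120 min replicate 2 (0.0803) or 40 min replicate 3 (0.128), and on its matching probe (-0.0034, 0.988). The ubiquitin match >196850 rose by 0.55 (adjusted p 0.0323), and lost its call in 5 of 18 fits, those without 120 min replicate 1, 2 or 3 (0.127, 0.0504 and 0.0550) or 40 min replicate 1 or 3 (0.0602 and 0.130), with slide as a term (0.0601) and on its matching probe (0.54, 0.0712). The thioredoxin match CHLRE_06g282651v5 rose by 0.48 (adjusted p 0.0326), and lost its call without 120 min replicate 1, 2 or 3 (0.0681, 0.0769 and 0.0867) or 40 min replicate 1 or 3 (0.0897 and 0.104), after normexp (0.26, 0.0744), in the authors' values (0.36, 0.0536) and on its matching probe (-0.16, 0.868). A ClpB match, CHLRE_11g467575v5, rose by 0.46 (adjusted p 0.0469). It lost its call in 14 of the 18 fits (up to 0.169), namely all but those without high light 480 min replicate 1, low light 0 min replicate 2 or 3, or low light 480 min replicate 2, and it changed by -0.38 (0.127) on its matching probe, number 1, since its values come from probe number 3. The same probe is taken when only probes number 1 and 2 are used. It also lost its call after normexp (0.33, 0.101) or quantile normalization (0.42, 0.0966), with replicate (0.0581) or slide (0.0712) in the model, and in the authors' values (0.20, 0.457).

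Camera found 2 lists shifted from 40 to 120 min. Cytosolic ribosomal proteins had a median of -0.27, with 8 of 26 called down over all genes and adjusted over the list alone (adjusted p 5.69e-06, estimated 0.707, slide term 1.82e-05, within-slide shifts -0.21, -0.37 and -0.32). After quantile normalization the median was -0.08 and the p was 0.312. Histones had a median of -0.55, with 77 called down over all genes and 82 adjusted over the list alone (adjusted p 3.54e-15, estimated 0.729, slide term 1.27e-12, within-slide shifts -0.98, -0.54 and -0.29). Joined to 1 mean per type their p was 0.210.

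Between 120 and 480 min the comparison followed the later phase. On the probes used the 4 genes of the heat shock and chaperone list were called down (3 on the matching probes), 120 of 137 histone models and 3 of 4 genes of cell cycle and DNA replication were called up, and the cytochrome c6 match rose further. Limma called 4351 of 13564 features, 1971 up and 2380 down, with 700 and 384 of them changed by a log2 of at least 1. The share called up was 45.3%, and 31.7% when the scaling percentile was taken over probes well above background on all arrays, which moved the median of all genes by -0.101. The groups did not overlap in 7212 features (53.4%, against 10% by chance). A fit with a slide term called 3119, and 99.9% of the called genes kept their direction within slide 2, the only slide that held both groups. By detection 19 features appeared and 21 disappeared.

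The cytochrome c6 match CHLRE_16g651050v5 rose by 2.05 from 120 to 480 min (SE 0.28, limma adjusted p 5.51e-05). The PCNA match CHLRE_12g515850v5 rose by 1.56 (SE 0.19, adjusted p 2.84e-05), the ribonucleotide reductase match CHLRE_12g491050v5 by 1.51 and the MCM helicase match CHLRE_03g178650v5 by 1.94 (SE 0.51, adjusted p 0.00889, or 0.0914 with slide as a term). The PSBS match CHLRE_01g016750v5 changed by -2.27, the elongation factor 2 match >107717 by -1.37, the chaperonin 60 match CHLRE_06g309100v5 by -1.32, the HSP70 match CHLRE_09g393200v5 by -1.16 and the ClpB match CHLRE_12g533351v5 by -1.04. Smaller falls were those of the starch synthase match CHLRE_17g721500v5 (-0.86), the glutamate semialdehyde aminotransferase match CHLRE_03g158000v5 (-0.78) and the ubiquitin match >196850 (-0.72, adjusted p 0.00635).

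Camera found 4 lists shifted from 120 to 480 min. Histones had a median of 0.88, with 120 of 137 called up over all genes and 130 adjusted over the list alone (adjusted p 7.95e-36, estimated 0.236, slide term 4.49e-28, shift within slide 2 of 1.27), and joined to 1 mean per type their p was 0.00418. Heat shock proteins and chaperones had a median of -1.10, with 4 of 4 called down over all genes and adjusted over the list alone (adjusted p 0.00519, estimated 0.0780, slide term 0.00288, shift within slide 2 of -0.96), and on the matching probes -0.72 (3 called down, adjusted p 0.0510, no call). Cytosolic ribosomal proteins had a median of -0.31, with 16 called down over all genes and 21 adjusted over the list alone (adjusted p 2.86e-05, estimated 0.379, slide term 3.8e-04, shift within slide 2 of -0.17), and after quantile normalization a median of -0.02 with a p of 0.832. Cell cycle and DNA replication had a median of 1.54 over 4 genes, with 3 called up over all genes and adjusted over the list alone (adjusted p 0.0314, estimated 0.236, slide term 0.0208, shift within slide 2 of 1.97). After quantile normalization this list had a p of 0.0510, and 0.0660 without 480 min replicate 1, and on the matching probes its adjusted p was 0.0967. The Calvin-Benson cycle list gained a call without 480 min replicate 2 (down, 0.0431 in place of 0.0846) and on the matching probes (down, 0.00345), and proteasome and ubiquitin without 120 min replicate 3 (down, 0.0481 in place of 0.0846).

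**Figure D3:**
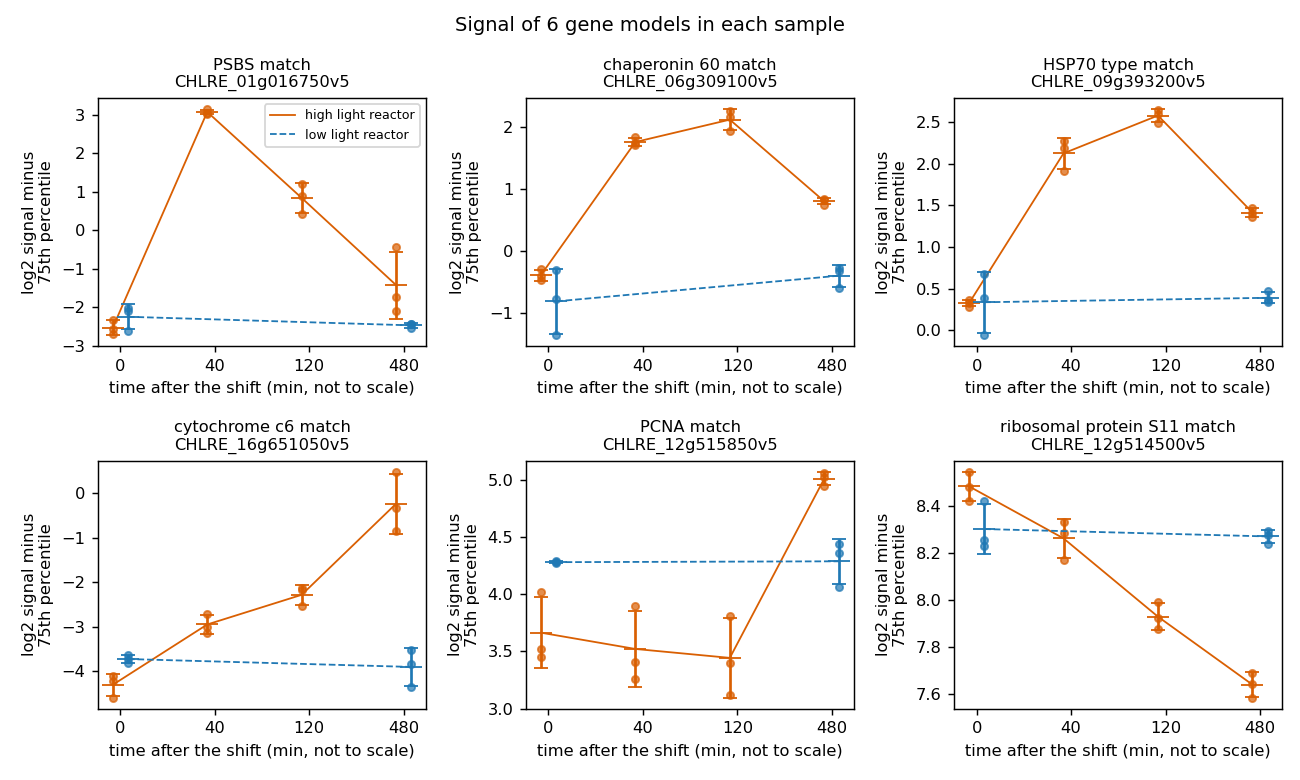
Log2 signal minus the array's 75th percentile of 6 gene models with a family match, against the time after the shift in min (not to scale), with 1 point per sample, lines through the group means, and bars of 1 standard deviation (n = 3). The PSBS match is highest at 40 min (5.61 above 0 min) and the cytochrome c6 match at 480 min (4.07 above 0 min, or 1.48 on the probe with the match).

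The low light reactor showed what 480 min did without a change in light. Its result rested on 1 sample. Limma called 0 of 13564 features, with the design as planned, with trend and robust variance, and with only the 6 samples fitted. An unadjusted p under 0.05 was reached by 3298 features, and the groups did not overlap in 2335 (17.3%, against 10% by chance). Without low light 0 min replicate 2 limma called 3945. With the slide as a term 0 were called, as with the replicate as a block, in a comparison in which the replicate numbers paired the samples. Only slide 4 held both groups. The PSBS match CHLRE_01g016750v5 changed by -0.22 (limma adjusted p 0.649) and the HSP70 match CHLRE_09g393200v5 by 0.05 (adjusted p 0.824). The Rubisco small subunit matches >108283 and CHLRE_02g120150v5 changed by -0.34 (adjusted p 0.155) and -0.28 (adjusted p 0.254). Without low light 0 min replicate 2 they changed by -0.45 (adjusted p 0.00748) and -0.43 (adjusted p 0.0373).

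Although no gene was called, camera found 3 lists shifted in the low light reactor. Histones had a median of 0.35, with 0 of 137 called over all genes and adjusted over the list alone (adjusted p 3.21e-29, estimated 0.435, slide term 7.79e-21, shift within slide 4 of 0.84), and joined to 1 mean per type their p was 0.0114. The median was 0.67 without low light 0 min replicate 2 and 0.21 without low light 0 min replicate 1. Cytosolic ribosomal proteins had a median of -0.26, with 0 called over all genes and 8 down adjusted over the list alone (adjusted p 1.2e-04, estimated 0.435, slide term 0.00754, shift within slide 4 of -0.24), but a median of 0.03 and a direction of up after quantile normalization (p 0.136), and a median of 0.08 in the authors' values. The Calvin-Benson cycle list had a median of -0.29, with 0 called over all genes and 2 down adjusted over the list alone (adjusted p 0.0321, estimated 0.435, shift within slide 4 of -0.45), but a direction of up after quantile normalization (p 0.814) and a median of 0.08 in the authors' values. Its p was 0.102 with slide as a term, 0.0537 with the replicate as a block, 0.150 without low light 0 min replicate 1 (median -0.17) and 0.0700 without low light 480 min replicate 2. On the matching probes the histones kept their call, while cytosolic ribosomal proteins (adjusted p 0.771) and the Calvin-Benson cycle (up, 0.0583) lost theirs and 3 other lists gained one.

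At 480 min the reactors were compared with each other, which set high against low light at the same elapsed time. The cytochrome c6, glutathione peroxidase and chaperonin 60 matches were higher in high light, and 25 of 26 ribosomal protein genes were called lower. Limma called 4210 of 13565 features, 2014 up in high light and 2196 down (47.8% up, or 40.9% after normexp), with 416 and 369 of them different by a log2 of at least 1. The groups did not overlap in 6186 features (45.8%, against 10% by chance). With a slide term 3243 were called, and at least 99.5% of the called genes kept their direction within slides 2 and 4. By detection 13 features appeared and 10 disappeared.

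The cytochrome c6 match CHLRE_16g651050v5 was higher by 3.67 in high light at 480 min (SE 0.28, limma adjusted p 5.5e-07, or 2.09 with 1.35e-04 on the matching probe) and the actin match CHLRE_03g176833v5 by 2.57 (SE 0.37, adjusted p 1.08e-04). The glutathione peroxidase match CHLRE_10g458450v5 was higher by 1.36, the chaperonin 60 match CHLRE_06g309100v5 by 1.2, the proteasome alpha subunit match CHLRE_01g030850v5 by 1.05, the stearoyl-ACP desaturase match CHLRE_14g630883v5 by 1.05 (but 0.24 with an adjusted p of 0.117 after normexp), and the HSP70 match CHLRE_09g393200v5 by 1.02 (but 0.27 with 0.0872 on the matching probe). The PSBS match CHLRE_01g016750v5 was higher by 1.05 (adjusted p 0.0190), but by 0.56 (0.0762) without high light replicate 3 and by 1.01 (0.0513) without low light 480 min replicate 3. Lower in high light were the matches to elongation factor 2 (>107717, -1.64), elongation factor 1 alpha (CHLRE_06g259200v5, -0.67, but -0.04 with 0.835 on the matching probe), thioredoxin (CHLRE_06g282651v5, -0.64, but -0.73 with 0.337 on the matching probe), ribosomal protein S11 (CHLRE_12g514500v5, -0.63) and the Rubisco small subunit (>108283, -0.52, or -0.12 with an adjusted p of 0.250 after quantile normalization). The biotin carboxylase match CHLRE_08g359350v5 differed by -0.86 (adjusted p 0.0436), and by 0.16 in the authors' values (adjusted p 0.487). It lost its call in 15 of the 18 fits that left out 1 sample (up to 0.154), namely all but those without high light 0 min replicate 2 or low light 0 min replicate 2 or 3.

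Camera found 1 list shifted between the reactors at 480 min. Cytosolic ribosomal proteins had a median of -0.48, with 25 of 26 called lower in high light over all genes and 26 adjusted over the list alone (adjusted p 1.39e-10, estimated 0.374, slide term 3.79e-09, within-slide shifts -0.44 and -0.47). After quantile normalization the median was -0.10 and the p was 0.0441. Heat shock proteins and chaperones missed the threshold (adjusted p 0.0698). This list was called up without high light 480 min replicate 2 (0.0489) or low light 0 min replicate 2 or 3 (0.0282 and 0.0338). The Calvin-Benson cycle list was called down without high light 480 min replicate 2 (0.0489 in place of 0.0947) and on the matching probes (0.00428).

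Before the shift, at 0 min, the reactors were compared as a background. Limma called 0 of 13564 features, with the design as planned, with trend and robust variance, with the slide as a term and with the replicate as a block, in a comparison in which the replicate numbers paired the samples. An unadjusted p under 0.05 was reached by 2879 features, and the groups did not overlap in 2343 (17.3%, against 10% by chance). Without low light 0 min replicate 2 limma called 3292. The PSBS match CHLRE_01g016750v5 differed by -0.28 (limma adjusted p 0.637) and the HSP70 match CHLRE_09g393200v5 by -0.01 (adjusted p 0.970). Camera found 0 of 11 lists shifted, 7 on the matching probes, and fry 1. Histones, at an adjusted p of 0.420, were called down without high light 0 min replicate 1 (4.41e-04), low light 0 min replicate 1 (2.88e-05) or low light 0 min replicate 3 (2.26e-08), and up without low light 0 min replicate 2 (1.11e-04).

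The last comparison took the 480 min change in the low light reactor from that in the high light reactor, which removes elapsed time and a constant offset between reactors. The cytochrome c6 and glutathione peroxidase matches rose more in high light, and 13 of 26 ribosomal protein genes were called as falling more. Limma called 3390 of 13564 features, 1762 up and 1628 down, with 635 and 565 of them different by a log2 of at least 1. Without low light 0 min replicate 2 the count was 4662. An unadjusted p under 0.05 was reached by 5072. The share called up was 52.0%, 48.7% in the authors' values and 37.6% when the scaling percentile was taken over probes well above background on all arrays, which moved the median of all genes by -0.125. Of these 3390 genes 3048 were also called in the same direction at 480 against 0 min in high light. With the slide as a term 2804 were called, and within slide 4, the only slide with all 4 groups, 99.8% of the called genes kept their direction.

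In this difference of changes the cytochrome c6 match CHLRE_16g651050v5 stood at 4.25 (SE 0.39, limma adjusted p 9.28e-06, or 2.25 with 0.00173 on the matching probe) and the actin match CHLRE_03g176833v5 at 2.76 (SE 0.52, adjusted p 0.00144). The glutathione peroxidase match CHLRE_10g458450v5 stood at 1.65 (adjusted p 3.97e-04), the PCNA match CHLRE_12g515850v5 and the proteasome alpha subunit match CHLRE_01g030850v5 at 1.34 each, the glutamate synthase match CHLRE_05g237100v5 at 1.23 and the HSP70 match CHLRE_09g393200v5 at 1.04. On their matching probes these 4 were uncalled, PCNA at 0.18 (0.869), the proteasome subunit at 0.47 (0.428), glutamate synthase at 1.19 (0.0582) and HSP70 at 0.0026 (0.993). The stearoyl-ACP desaturase match CHLRE_14g630883v5 stood at 1.2 (adjusted p 0.0228). The call was lost without high light 0 min replicate 2 (0.0610), high light 480 min replicate 3 (0.0567), low light 0 min replicate 1 (0.0609) or low light 480 min replicate 3 (0.0529), and with slide as a term (0.0760). It was also lost after normexp (0.38, 0.0951), on probes number 1 and 2 (0.55, 0.337) and in the authors' values (0.66, 0.132). The PSBS match CHLRE_01g016750v5 stood at 1.33 (SE 0.44, adjusted p 0.0395). It lost its call with slide as a term (0.0547), after normexp (0.91, 0.0748) and in 9 of the 18 fits that left out 1 sample (0.0508 to 0.0814). These were the fits without high light 0 min replicate 1 or 2, 120 min replicate 2 or 480 min replicate 3 (then 0.84), low light 0 min replicate 1 or 3, or any low light 480 min sample.

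On the falling side of this difference were the matches to elongation factor 2 (>107717, -2.40, SE 0.29, limma adjusted p 7.39e-05), thioredoxin (CHLRE_06g282651v5, -1.24, adjusted p 0.00102, but -0.40 with 0.750 on the matching probe) and dyskerin (CHLRE_03g172950v5, -1.12, adjusted p 0.0109, or -0.17 with 0.736 in the authors' values). The biotin carboxylase match CHLRE_08g359350v5 stood at -1.81 (adjusted p 0.00697), and at 0.35 (adjusted p 0.268) in the authors' values. The 2-Cys peroxiredoxin match CHLRE_17g743897v5 stood at -1.12 (adjusted p 0.0299), and at -0.70 (0.0176) without low light 0 min replicate 3. It lost its call in 6 of the 18 fits, those without high light 0 min replicate 1 or 2 (0.0501 and 0.0677), high light 480 min replicate 2 or 3 (0.0541 and 0.0631), or low light 480 min replicate 2 or 3 (0.0742 and 0.0588). With an ID only, CHLRE_13g603550v5 stood at -6.38. Camera found 1 list shifted, cytosolic ribosomal proteins, with a median of -0.43, 13 called down over all genes and 16 adjusted over the list alone (adjusted p 7.12e-08, estimated 0.420, slide term 4.34e-06, shift within slide 4 of -0.19). After quantile normalization the median was -0.11 and the p was 0.0232. On the matching probes the Calvin-Benson cycle list was called down as well (3.14e-04). Without low light 0 min replicate 2 histones were called down as well (0.00211 in place of 0.872), as were translation factors and tRNA synthetases (0.0233 in place of 0.0685), which were also called without low light 480 min replicate 1 (0.0318).

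The families of the Rubisco small subunit and carbonic anhydrase were to be reported in every comparison, called or not, and what follows completes them. At 120 against 0 min the Rubisco small subunit match CHLRE_02g120150v5 changed by -0.25 (limma adjusted p 0.206, but -0.35 with 0.0094 on the matching probe) and the match >108283 by -0.34 (adjusted p 0.0197). The latter lost its call with slide as a term (0.0768), without 0 min replicate 2 or 3 (0.0528 and 0.0775) and without 120 min replicate 2 or 3 (0.0750 and 0.0549), and stood at 0.012 (0.916) after quantile normalization and at -0.18 (0.0728) in the authors' values. From 40 to 120 min they changed by -0.15 (adjusted p 0.527) and -0.28 (adjusted p 0.0725, or 0.0318 without low light 0 min replicate 2). From 120 to 480 min they changed by -0.48 (adjusted p 0.0231) and -0.41 (adjusted p 0.00975), and with slide as a term the adjusted p was 0.0970 and 0.0718. Both calls ended and the changes shrank after quantile normalization, to -0.19 (0.139) and -0.12 (0.226), and in the authors' values, to -0.19 (0.0706) and -0.15 (0.155). Without 120 min replicate 1 or 3 or 480 min replicate 1 CHLRE_02g120150v5 was uncalled there (0.0611, 0.111 and 0.0933). Between the reactors it differed by -0.46 at 480 min (adjusted p 0.0294), and was uncalled with slide as a term (0.0899), without high light 480 min replicate 1 or 3 (0.102 and 0.0592) or low light 480 min replicate 1 or 3 (0.0919 and 0.0789). It shrank to -0.04 (0.781) after quantile normalization and -0.07 (0.518) in the authors' values. At 0 min the reactors differed by -0.01 (adjusted p 0.983) and, for >108283, by -0.11 (adjusted p 0.603). The difference of the 480 min changes was -0.46 (adjusted p 0.133, but -1.0 with 1.71e-04 on the matching probe) and -0.42 (adjusted p 0.0614), the latter called without high light 480 min replicate 2 (0.0462) or low light 0 min replicate 1 (0.0328), after normexp (-0.42, 0.0448) and in the authors' values (-0.33, 0.0399).

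The carbonic anhydrase match CHLRE_03g145067v5, read on the strand opposite to its probe, was up by 0.88 at 120 against 0 min (limma adjusted p 1e-04), where the authors' values gave 0.04 (adjusted p 0.874). It changed by 0.16 from 40 to 120 min (adjusted p 0.416) and by -0.25 from 120 to 480 min (adjusted p 0.179), where the authors' values gave 0.53 (adjusted p 0.0184). In high light at 480 min it was above low light by 0.54 (adjusted p 0.00644), and the difference of the 480 min changes was 0.95 (adjusted p 0.00231). In the low light reactor it changed by -0.31 (adjusted p 0.184), or by -0.49 (0.00772) without low light 0 min replicate 2. At 0 min the reactors differed by -0.41 (adjusted p 0.151), or by -0.58 (0.00278) without low light 0 min replicate 2.

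The 3 comparisons against 0 min in the high light reactor called 9347 features between them. Of these 1051 were up and 1214 down at all 3 times, while 1443 were called at 40 min only, 727 at 120 min only and 1604 at 480 min only. At 40 and 120 min, 3711 features were called in the same direction and 81 in opposite directions. At 40 and 480 min these counts were 2763 and 484, and at 120 and 480 min 3217 and 283. Independent lists of the same sizes would share 1238, 1332 and 1218. The comparisons use the same 0 min samples, whose chance deviations enter every change. Simulated groups without change against the same controls shared 0 calls, which sets no baseline, as few arise without change. Their correlation across genes was 0.497 and covariance 0.0250 for 40 and 120 min, where the data gave 0.776 and 0.457. For 40 and 480 min the data gave 0.514, close to the simulated 0.497, and 0.286 against 0.0250. For 120 and 480 min they gave 0.624 against 0.499, and 0.286 against 0.0251. With the low light 0 min samples as control of the later time the shared counts were 3526, 2675 and 3187. As control of the earlier time they gave 3707, 2561 and 2877. The replicate numbers correlated between the reactors at 0 min (0.136, 0.120 and 0.249), so these controls are other samples but not independent ones, and the simulation left this pairing out.

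The other 5 of the 11 lists tested were called in none of the 9 comparisons by camera. Their lowest adjusted p values were 0.113 for antioxidants and peroxide removal, 0.205 for cytochrome b6f and electron carriers, 0.260 for fatty acid and lipid synthesis, 0.0934 for mitochondrial respiration and 0.0685 for translation factors and tRNA synthetases.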

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

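The tests of a wrong label and of normalization below were chosen only after the result was seen, and so were the final criteria for a signal-dependent response. The changes from 0 to 480 min were compared between the 2 reactors with an interaction term in limma, and 3390 genes were singled out because their change in high light differed from that in low light. The median of this difference over the 26 cytosolic ribosomal protein genes was -0.43. Of 100 splits of the samples drawn at random, the real one included, 2 gave as many genes as the 3390 of the real split, the highest other giving 4035. The splits exchanged samples between the reactors at both times, so they also undid the difference between the reactors at 480 min. They ignored the pairing by replicate number as well. The split with 4035 kept the 480 min samples of each reactor together and mixed those at 0 min. The share therefore does not decide on chance for the difference of changes. For the gene lists 93 of the 100 splits gave as many as the 1 list of the real split, the highest other 5, so chance is not excluded there either. The light and the reactor go together in the design, and the interaction cannot separate them.

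Named genes were singled out for the same reason, a change that differed between the reactors. Above the low light change were the matches of cytochrome c6 CHLRE_16g651050v5 by 4.25, actin CHLRE_03g176833v5 by 2.76, glutathione peroxidase CHLRE_10g458450v5 by 1.65, PCNA CHLRE_12g515850v5 by 1.34, a proteasome alpha subunit CHLRE_01g030850v5 by 1.34 and PSBS CHLRE_01g016750v5 by 1.33. Glutamate synthase CHLRE_05g237100v5 followed with 1.23, the desaturase CHLRE_14g630883v5 with 1.2, HSP70 CHLRE_09g393200v5 with 1.04 and carbonic anhydrase CHLRE_03g145067v5, matched on the strand opposite to its probe, with 0.95. Below it were the matches >107717 at -2.40, CHLRE_08g359350v5 (biotin carboxylase) at -1.81, CHLRE_06g282651v5 at -1.24, CHLRE_03g172950v5 at -1.12 and CHLRE_17g743897v5 at -1.12, and the feature CHLRE_13g603550v5 at -6.38. Of these genes 3 lost their call with 1 sample left out. For CHLRE_01g016750v5 these were high light 0 min replicate 1 or 2 (adjusted p 0.0785 and 0.0746), 120 min replicate 2 (0.0508) and 480 min replicate 3 (0.0546), low light 0 min replicate 1 or 3 (0.0807 and 0.0814), and low light 480 min replicate 1, 2 or 3 (0.0570, 0.0706 and 0.0713). For CHLRE_14g630883v5 they were high light 0 min replicate 2 (0.0610), high light 480 min replicate 3 (0.0567), low light 0 min replicate 1 (0.0609) and low light 480 min replicate 3 (0.0529). For CHLRE_17g743897v5 they were high light 0 min replicate 1 or 2 (0.0501 and 0.0677), high light 480 min replicate 2 or 3 (0.0541 and 0.0631) and low light 480 min replicate 2 or 3 (0.0742 and 0.0588). After normexp CHLRE_01g016750v5 (0.91) and CHLRE_14g630883v5 (0.38) were uncalled, and with slide as a term as well. In the authors' values CHLRE_14g630883v5 (0.66) and CHLRE_03g172950v5 (-0.17) were uncalled and CHLRE_08g359350v5 stood at 0.35, the opposite direction. The values of 8 of these models come from another probe than the one with the match. On the matching probe 5 were uncalled, CHLRE_12g515850v5 at 0.18, CHLRE_01g030850v5 at 0.47, CHLRE_05g237100v5 at 1.19, CHLRE_09g393200v5 at 0.0026 and CHLRE_06g282651v5 at -0.40.

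A signal was also seen outside the measurement that the comparisons use. In 912 models probe number 3 lies over the other probes on the opposite strand. Of the 745 such probes that the comparisons do not use, 33.4% (249) were well above background on all arrays, against 0 of 153 negative control spots. Among all 912 the share was 42.8% (390), and their median level was -2.91 on the log2 scale against the brighter of probes 1 and 2, with 188 brighter than both. Among the probes with a family match the protein was read on the probe's own strand for 164 of number 1 and 187 of number 2, and on the opposite one for 1 and 0. For number 3 it was the opposite strand in 128 and the own one in 42. For models without a match the strand was not tested.

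The first pattern weighed is the 5999 genes called at 40 against 0 min in high light. The number of calls had been seen when the tests were set, but not their outcome. Groups without overlap fix the direction within slides (99.3% kept), so only the slide term bears on a slide effect. Array scaling is argued against, since 91.2% of the calls kept their call and direction after quantile normalization. Of the features well above background on all arrays 45.6% were called (5444 of 11950), against 44.2% of all tested. Most tested features are among them, so dim probes are not decided on. With 3 samples per group the 10 splits are too few for a share under 0.05. The real split called 5999, the highest other 0. A response to light stays open as a hypothesis. No low light sample was taken at 40 min, so time and light cannot be separated. No biological explanation was tested.

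For the other comparisons of 3 with 3 samples the 10 splits are likewise too few for a share under 0.05. The real split gave 5536 genes at 120 against 0 min, 5868 at 480 against 0 min and 4351 at 480 against 120 min, the highest other 0 in each. For 120 against 40 min it gave 3821, the highest other 1, and between the reactors at 480 min 4210, the highest other 0. In each of these only the real split of 10 gave as many genes. For the lists, 4 splits at 40, 120 and 480 against 0 min gave as many as the real 2, 4 and 3, the highest other 4 in each. From 40 to 120 min 6 splits gave as many as the real 2 (highest other 3), and from 120 to 480 min 3 gave as many as the real 4 (highest other 5). For low light 1 split gave as many as the real 3 (highest other 2). Between the reactors 10 splits gave as many as the real 1 at 480 min (highest other 3), and 10 as many as the real 0 at 0 min, which a count of 0 fixes (highest other 4).

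The next pattern weighed is the low light reactor, where limma called 0 genes at 480 against 0 min while 3298 had an unadjusted p under 0.05. One deviating sample has the value it needs. Without low light 0 min replicate 2 the count was 3945, and without each of the other 5 samples it was 0. Without that sample the comparison of the reactors at 0 min called 3292 genes in place of 0, with 2879 at an unadjusted p under 0.05 in the full data. A slide effect is not decided by the 0 genes called with slide as a term (3191 at an unadjusted p under 0.05). Only slide 4 held both groups. With a real count of 0 all 10 splits give as many genes by construction, which decides nothing, but the split of low light 0 min replicates 1 and 3 with 480 min replicate 1 against the rest called 2742. This points to a structure of the samples other than the groups. At 0 min between the reactors the 10 of 10 splits are likewise fixed by a real count of 0, and the split that puts low light replicate 2 with high light replicates 1 and 2 called 898, which points the same way.

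A wrong label on low light 0 min replicate 2 stays open. It lay 0.289 from the mean of the high light 0 min samples (root mean square of log2 differences), within the 0.313 of that group's own samples, and 0.332 from the low light 480 min samples, whose own reach 0.386. From the mean of its 2 fellows it lay 0.562. By the criterion first written this counts for a wrong label, but groups held at the same light before the shift may be alike, so the distance was taken not to decide. No partner for a swap was found, since each of the other samples lay nearest to its own group. The same values would arise if replicates 1 and 3 were the deviating ones, and theirs were the arrays with the lowest 75th percentile of intensity, 429 and 496. The 2 readings cannot be told apart.

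The last pattern weighed is the fall of cytosolic ribosomal protein genes at 480 against 0 min in high light (median -0.70 over 26 genes). Bright probes fell on average, so 10000 random lists matched on mean signal were drawn, with a median of -0.61 and a central 95% from -0.69 to -0.51. The list lay at percentile 1.24. By the criterion first written this argues against a signal-dependent array response, but the upper bound of the list's own spread, -0.686, overlaps the lower bound of the matched lists, -0.692, so it is left open. For the difference between the reactors at 480 min the percentile was 0.03 and for the difference of the changes 0.44. Most of the fall is shared by matched genes. Normalization stays open as well. The list was lower than the other genes under each scaling, by a log2 median of -0.59 as reported, -0.42 after normexp, -0.13 in the authors' values and -0.0708 after quantile normalization. Camera's adjusted p was 0.0704 after quantile normalization and 0.321 with the correlation estimated from the data (0.543). A fall of these genes beyond that of other bright genes and a change in the arrays' response cannot be told apart, and no biological explanation was tested.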

How the results depend on the processing

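The numbers of genes called moved by at most 1.5 times in 122 of 129 repeats under other settings, and the 6 overlap values stayed in range. Testing all probes singly counts probes, not genes, and gave 14996 at 40, 13071 at 120 and 13942 at 480 min against 0 min. From 40 to 120 and 120 to 480 min it gave 8837 and 10464. It gave 9862 between the reactors at 480 min and 7702 for the difference of changes. With 1 sample left out the counts stayed within 1.5 times in 160 of 162 repeats. They ranged from 5300 to 6512 at 40 min, 4431 to 6159 at 120 min and 4642 to 6563 at 480 min against 0 min, 2837 to 4415 from 40 to 120 min, 3271 to 5034 from 120 to 480 min, 3232 to 4911 between the reactors at 480 min and 2477 to 4662 for the difference of the changes. In low light the range was 0 to 3945 and between the reactors at 0 min 0 to 3292, both highest without low light 0 min replicate 2, the sample weighed above as deviating or wrongly labelled.

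The numbers of lists called by camera were less stable, with 57 of 81 repeats within 1.5 times, and the cause was not tested except that the estimated correlation (0.543 for the ribosomal list) widens the test by construction. With it the count was 1 at 120 min and 0 in the other comparisons. Fry gave 4 at 40 min, 8 at 480 min, 9 from 120 to 480 min, 8 and 1 between the reactors at 480 and 0 min and 8 for the difference of the changes, and asks another question. Quantile normalization gave 1 at 480 min, 1 from 40 to 120 min, 1 in low light and 3 between the reactors at 480 min. Slide as a block gave 2 for the difference of the changes, and joined histones 1 from 40 to 120 min. The probes with the family match gave 1 at 40 min, 2 and 7 between the reactors at 480 and 0 min and 2 for the difference of the changes. Of the 20 list calls, 14 were called in the same direction on these probes, 12 were called in the same direction after quantile normalization, 19 with slide as a term, 19 with replicate as a block, 17 with histones joined and 1 with the estimated correlation. With 1 sample left out the count was within 1.5 times in 153 of 162 repeats, ranging from 1 to 3 between the reactors at 480 min and for the difference of the changes, and from 0 to 1 between the reactors at 0 min.

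The replicate block, which treats equal replicate numbers as pairs, kept 133 of the 135 named values on their side of the threshold, slide as a term 124, normexp 128, quantile normalization 126, probes number 1 and 2 (added after the data were seen) 131 and the authors' values 116. Leaving out 1 sample kept 117 in both the lowest and the highest value. The probe with the family match, added after the data were seen, kept 54 of the 77 values it could change. Of 1157 such values 1046 were kept, 96 lost the call, 4 gained it and 11 changed sign. These were, with the cause not tested, >108283 at 120 against 0 min after quantile normalization (0.012), CHLRE_08g359350v5 in the authors' values at 480 against 0 min (0.16), between the reactors at 480 min (0.16) and for the difference of the changes (0.35), CHLRE_03g145067v5 from 120 to 480 min in the authors' values (0.53), and CHLRE_11g467575v5 from 40 to 120 min on probes 1 and 2 and on the matching probe (-0.38). On the matching probe CHLRE_06g282651v5 changed sign at 40 (0.028) and 480 min (0.12) and from 40 to 120 min (-0.16), and CHLRE_09g393200v5 from 40 to 120 min (-0.0034). Over all 237 values of the naming rule 1731 of 2026 were kept, 260 lost the call, 4 gained it and 31 changed sign. The 102 values left out of the text held 20 of these 31, so the named values are the steadier part.

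Signal over background limits the dim features. Of 14575 features 13565 passed the filter, and 11950 of these were well above background on all arrays. A change of a dim feature in a group not above background rests on surrogate intensities, and its size is uncertain.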

Other observations

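The test below was chosen before its result was seen. Genes next to each other on a chromosome, in the order of the reference table, were asked whether they change together at 40 against 0 min. Over 7953 adjacent pairs the log2 changes correlated at 0.111 (0.0987 by rank), above the 0.0430 that was the highest of 1000 shuffles of the gene order within chromosomes. The 61 pairs that share probe sequence were left out. Genes 2 apart correlated at 0.0126. Of 256 pairs with both genes called at a log2 of at least 1, 175 (68.4%) changed in the same direction. The effect is small, and shared regulation, a shared promoter and copies of a gene too diverged to share 15 bases are hypotheses that were not tested.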
